A study of Homo sapiens with 10 samples.

How the data were processed

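RNA from GIST-T1 cells, an established human cell line derived from a gastrointestinal stromal tumour (GIST), was profiled by RNA sequencing in 10 libraries. The groups were the control line (genotype given as wild type) and 4 derivative lines with a disrupted CTCF insulator, named InsE, InsF, InsG and InsH, with 2 libraries per group. CTCF is the DNA-binding protein that marks many boundaries between chromosome loops. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with the NEBNext Ultra II RNA kit. The labels do not say what was edited in each letter-named line, whether the lines were clones, or whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

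The authors deposited 1 table of estimated (expected) counts and TPM (transcript shares corrected for length) per library, with 58381 gene rows each. Per the submitters' processing notes, STAR 2.5.3, RSEM 1.3.2 and DESeq2 1.38.3 were used with the genome build hg38. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited expected counts are RSEM's estimates of fragments per gene, not normalised between libraries. Of all 58381 values per library, zeros included, 10.2% to 12.8% were not whole numbers. Only 19385 to 23012 genes per library had a count, so the share among detected genes was higher. The deposited TPM values sum to the same total in each library and keep no depth. A further table of the series with 10 value columns was not used here, because its column names did not match the labels.

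Gene symbols were those of the deposited tables. Positions and gene types came from GENCODE release 29, to which 58261 of the 58381 rows matched by Ensembl identifier, 56933 of them with the same version. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart, as for CCND1 and ORAOV1 (now LTO1), which overlap at their ends. Genes with near-identical copies, such as SULT1A1, EIF5AL1, the clustered protocadherins, ribosomal protein genes and mitochondrial genes, are uncertain to the extent that RSEM split their reads.

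Library totals ran from 9.4 to 42.5 M (mega) expected counts. Those of replicate 1 held 22.9 to 42.5 M and those of replicate 2 held 9.4 to 20.1 M. A count of 0 was read as a level of up to 3 counts. For the pair of control libraries, with 50.9 M counts, this floor was 0.0608 CPM (counts scaled by library size), and folds against a control at 0 were computed as lower bounds from it. Floors and 95% intervals cover counting error only.

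Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 after TMM normalisation and edgeR's expression filter (minimum count of 10), which left 15554 genes. All 10 libraries were fitted together, leaving 5 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Contrasts were each line against control, the mean of the 4 lines against control, any difference among the 4 lines, and each of the 5 groups against the mean of the others. Fold changes are given on the log2 scale with SE, levels as mean CPM ± SD with n = 2 libraries per group. Gene lists were 30 in number, and 25 with at least 5 tested members were tested with camera (limma 3.58.1, inter-gene correlation of 0.01, log2 CPM with a prior count of 2) and adjusted over the lists of a comparison. An estimated correlation and fry, which tests whether a list's genes moved one way on balance, served as checks. Calls near FGF3 were compared with those elsewhere by Fisher's exact test.

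Genes named in the text were chosen by a rule. It took all measured genes of 2 lists at the FGF3 and ANO1 locus. It took up to 8 genes with the largest rise and 8 with the largest fall per line, and 10 and 10 for the mean of the lines. These had to pass the threshold, have a mean log2 CPM of at least 1, lie beyond both control libraries in every line library, and carry a symbol that is not a clone name or pseudogene. It took the 5 genes with the smallest p among the lines, and from each list up to 4 called members with the largest change or, where none was called, the 2 with the highest level. The text prints part of the list members so chosen. A further 2 were removed from the named genes, are not reported here, were not replaced, and stayed in the tests of all genes and of the lists. A few further genes are named and marked as chosen after their values were seen. The rule, the lists, the tests and most alternatives were fixed before the data were examined.

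The pipeline was tested on simulated counts with 200 changed genes, drawn from the tested genes with a mean of at least 1 CPM. For InsE against control, edgeR recovered 65.7% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 90.9% of those changed 4-fold, with 19 false calls among 174. The 2 control libraries differed by more than sampling noise over genes with whole counts (chi-square 1.12 per degree of freedom, p = 1.87e-14), far less than the libraries of a line did (4.48 to 5.53). They were kept as 2 replicates. Libraries of the same RNA could also exceed sampling noise, so this test does not show that they came from separate cultures. Alternatives were RLE, upper quartile and no normalisation factors, other filters, unrounded counts, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a replicate block, other thresholds, pairs of groups alone and leaving out each library. A block within the 4 lines and merging both control libraries into 1 were added after seeing the data. To show what correlation and covariance of the changes shared controls give by chance, 30 data sets without any change were simulated with the fitted dispersions.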

Results

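The series asked how disruption of a CTCF insulator changed gene expression in GIST-T1 cells, a GIST line with intact succinate dehydrogenase (SDH). The control line and the 4 insulator-disrupted lines InsE, InsF, InsG and InsH had 2 libraries each. The control libraries held 30.8 and 20.1 M (mega) expected counts, those of InsE 31.0 and 9.4 M, of InsF 28.8 and 14.8 M, of InsG 42.5 and 11.1 M, and of InsH 22.9 and 12 M. The name of the deposited data (FGFins) points to an FGF insulator and does not name a single gene. FGF3, chosen here, and its neighbours on the long arm of chromosome 11 are described first.

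FGF3, a fibroblast growth factor gene, went from no counts in the control to a clear level in all 4 lines. FGF3 (chromosome 11, 69809969 to 69819024, minus strand, hg38) had 0 counts in both control libraries, which held 50.9 M counts together. It had 1482 counts over both InsE libraries, 575 in InsF, 284 in InsG and 295 in InsH. The level was 36.3 ± 0.32 CPM in InsE, 13.4 ± 1.2 in InsF, 5.34 ± 0.18 in InsG and 8.87 ± 2.2 in InsH (SD, n = 2 each). Against the floor of 3 counts over both control libraries, FGF3 was at least 596-fold higher in InsE, at least 220-fold in InsF, at least 87-fold in InsG and at least 145-fold in InsH. The edgeR adjusted p was 1.3e-06, 1.9e-06, 1.4e-05 and 6.6e-06 in that order.

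**Figure D1:**
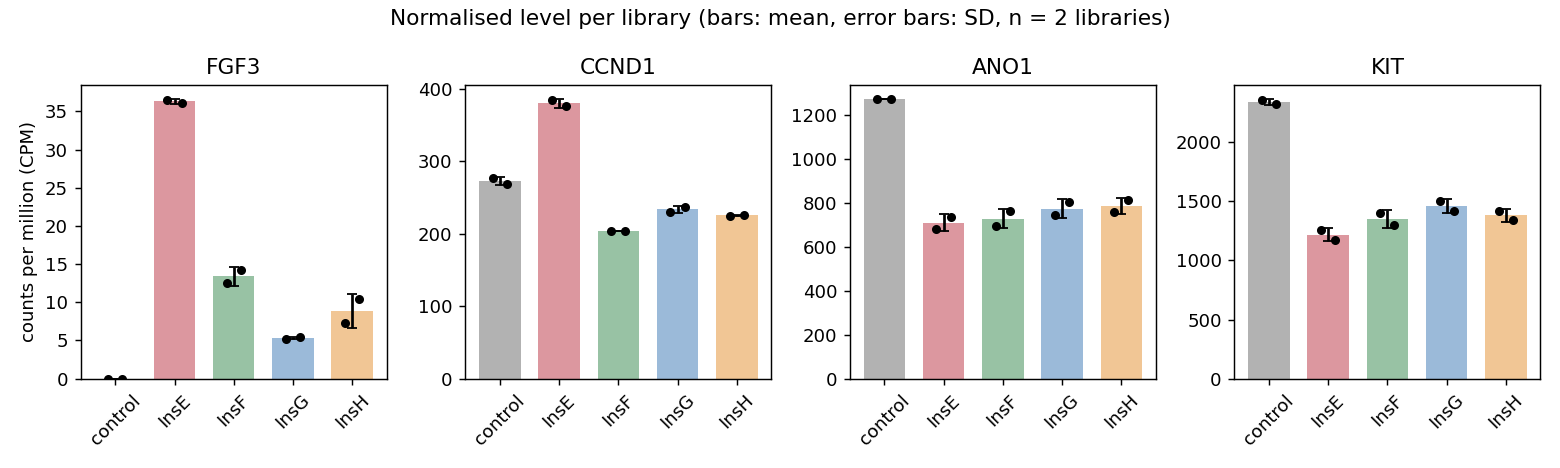
Normalised level (CPM) of FGF3, CCND1, ANO1 and KIT per library, with bars for the mean of 2 libraries, error bars for the SD and points for the libraries. FGF3 was at 0 in both control libraries and at 36.3 CPM in InsE, and ANO1 was at 1274 CPM in the control and at 711 to 786 CPM in the 4 lines.

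The lines differed in their FGF3 level (edgeR adjusted p = 4.13e-05 among the 4 lines). InsE exceeded InsF 2.73-fold, InsG 6.85-fold and InsH 4.2-fold. InsF exceeded InsG 2.51-fold and InsH 1.54-fold. All of these and the difference of InsG from InsH passed the threshold in edgeR after adjustment over the 6 pairs, with a largest adjusted p of 0.00342. Adjusted over all genes, 0 genes passed between InsG and InsH and 11 between InsF and InsH, and FGF3 was not among them.

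On the FGF3 side of the locus, ORAOV1 (LTO1) rose in all 4 lines, and FGF19 and MYEOV rose from near 0 in the mean of the lines. ORAOV1 rose by 0.67 ± 0.07 (log2 ± SE) in InsE and by 0.44 to 0.50 in the others, where the call in InsG was lost without InsG replicate 1 (adjusted p = 0.0503). Its end overlaps that of CCND1 on the other strand, so reads there cannot be assigned without a strand setting. FGF19, another FGF gene, had 41, 18, 14 and 13 counts in InsE, InsF, InsG and InsH against 4 in the control, a 12.4-fold ratio in InsE (95% counting interval 4.5 to 47.7). MYEOV had 16, 25, 33 and 16 counts against 6. In single lines, FGF19 did not pass in InsG and InsH (edgeR adjusted p = 0.111 and 0.0627), nor MYEOV in InsE and InsH (0.0805 and 0.0664). FGF4 had 0 control counts and 1, 2, 12 and 3 line counts, and was too low to test. CCND1, the cyclin D1 gene, rose by 0.48 ± 0.05 in InsE and fell by 0.42 in InsF, by 0.22 in InsG and by 0.28 in InsH, a difference among the lines (edgeR adjusted p = 1.16e-05). Its call in InsG was lost without control replicate 1 (adjusted p = 0.0943). For the mean of the lines, the calls of CCND1, TPCN2 and MYEOV were lost without control replicate 1 (adjusted p = 0.338, 0.374 and 0.221), and that of FGF19 without control replicate 2 (0.112). Over the 6 tested genes of the FGF3 side, 5 rose and 1 fell in the mean of the lines, as many as when adjusted over the list alone (camera adjusted p = 0.00414). The adjusted p = 0.124 with an estimated correlation. FGF3 itself is among the 5 and enters this test, so the test does not speak for its neighbours alone.

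On the other side, ANO1, the chloride channel gene whose protein (DOG1) marks GIST, fell by a similar amount in each line. ANO1 (chromosome 11, 70078302 to 70189528) stood at 1274 ± 0.63 CPM in the control. It stood at 711 ± 39 in InsE, 729 ± 45 in InsF, 775 ± 41 in InsG and 786 ± 37 in InsH. The log2 changes were -0.84, -0.81, -0.72 and -0.70, each with an SE of 0.06. The test among the lines, without a term for the replicate number, gave an edgeR adjusted p of 0.326. In both replicates the level rose in the order InsE, InsF, InsG and InsH, so this test does not show that the falls were equal. SHANK2, PPFIA1 and CTTN fell in the mean of the lines by 0.92, 0.21 and 0.18, and FADD rose by 0.21. Without a control library these 4 calls were lost (adjusted p = 0.108 without control replicate 2 for SHANK2, and 0.112, 0.183 and 0.229 without control replicate 1 for PPFIA1, CTTN and FADD). Of the 5 genes of this side, 4 fell and 1 rose, as many as when adjusted over the list alone (camera adjusted p = 0.0428). The adjusted p = 0.29 with an estimated correlation.

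**Figure D2:**
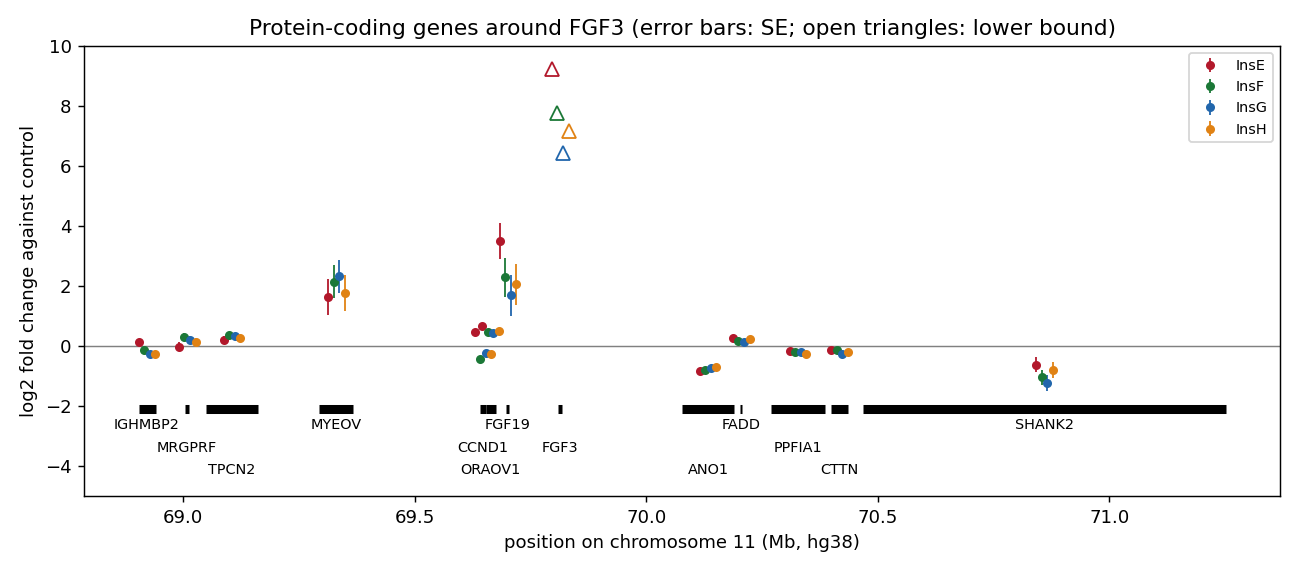
Log2 fold change of each line against control for tested protein-coding genes around FGF3, by position on chromosome 11 (Mb, hg38), with error bars for the SE and black bars for gene bodies. FGF3 is drawn at its lower bound (open triangles, at least 87-fold to 596-fold), FGF19 and MYEOV lie above 0 and ANO1 lies below 0 in the 4 lines.

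Genes near FGF3 were called more often than genes elsewhere. Of 36 tested genes within 2 Mb, 20 changed in the mean of the lines (8 up, 12 down), or 55.6% against 27.6% elsewhere (odds ratio 3.29, Fisher's exact p = 0.000506). The exact test takes neighbouring genes as independent, which they may not be. The called genes include FGF3 itself and the antisense genes RP11-805J14.2 and RP11-805J14.5. These overlap ANO1 and FADD, so their reads cannot be assigned without a strand setting. Several of the calls, as given above, were lost without a control library. For single lines, 12 of the 36 changed in InsE (p = 0.166), 15 in InsF (0.00838), 14 in InsG (0.011) and 12 in InsH (0.0295), by the same exact test. The clone-named lncRNA RP11-626H12.1 between FGF3 and ANO1, chosen after its values were seen, fell from 11.6 CPM to 4.54 in InsE and to 5.09 to 5.68 in the other lines. Within 5 Mb (181 genes) the odds ratio for the mean was 1.24 (exact p = 0.182).

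Beyond the locus, many genes changed in the mean of the 4 lines against control. With a single control line, this contrast cannot separate the disruption from what else sets that line apart. DCN (decorin) and POSTN (periostin), both secreted matrix proteins, rose by 4.34 ± 0.10 and 3.88 ± 0.14, from 1.01 and 0.803 CPM in the control to 31.1 and 12.9. DCN stood at 2.59 CPM in InsE (log2 1.41) and at 36.5 to 44.6 CPM in the other lines, which carry most of its mean change. PDZRN4 (3.36), YBX3 (3.22), IGF2BP1 (3.10), PSTPIP1 (3.04), CAPN6 (2.98), SULT1A1 (2.92) and HSPB8 (2.70) also rose. CNTNAP2, a neurexin family adhesion gene, fell by 2.54 ± 0.11, from 22.4 to 3.86 CPM. MMP1, an interstitial collagenase, fell by 2.17 ± 0.08. MAP4K1 (-2.41), PPP1R3B (-1.90), P3H3 (-1.85), DSP (-1.81), BEND4 (-1.79), FAM19A5 (-1.71), KCNC1 (-1.68) and MOXD1 (-1.63) fell too.

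In all, 4296 of 15554 genes changed in the mean (2039 higher, 2257 lower), of which 591 by 2-fold or more (389 higher, 202 lower). The count rested on both control libraries, being 1501 without control replicate 1, 1685 without control replicate 2 and 1690 with both merged into 1, an alternative added after seeing the data. The split depended on the scaling. It was 2806 higher and 1699 lower with library sizes alone, and 1326 higher and 747 lower with limma on log2(TPM + 1).

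In InsE against control, the matrix gene POSTN rose and the matrix genes TNC and ECM1 fell. After FGF3, the largest rises were those of PDZRN4 (3.17 ± 0.41), POSTN (3.10 ± 0.17), EIF5AL1 (2.73 ± 0.73), ZNF529 (2.64), CAPN6 (2.5), MAOB (2.35) and AGMO (2.26). PRSS35, a secreted protease-like gene, fell by 4.99 ± 0.41, to 0.064 ± 0.091 CPM. That level lay below the floor of 0.319 CPM of InsE replicate 2, so the size of this fall is not settled. MMP1 fell by 3.45, the desmosome gene DSP by 3.28, and the matrix genes TNC and ECM1 by 3.06 and 2.92. The interferon-induced GTPase gene GBP2 fell by 2.86, CNTNAP2 by 2.68 and SLIT3 by 2.60. The call of EIF5AL1 was lost without InsE replicate 1 (adjusted p = 0.284). In InsE 3611 genes changed (1675 higher, 1936 lower), 1429 without control replicate 1, 1614 without control replicate 2 and 1966 without InsE replicate 1. With library sizes alone the split was 2299 higher and 1520 lower.

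InsF, InsG and InsH shared their leading genes. DCN rose by 5.45 ± 0.10, 5.17 ± 0.11 and 5.32 ± 0.11 in InsF, InsG and InsH, from 1.01 ± 0.046 CPM to 44.6 ± 1.2, 36.5 ± 0.51 and 40.6 ± 0.66. GFRA1, a co-receptor for the growth factor GDNF, rose by 4.95, 4.82 and 4.73, POSTN by 4.44, 3.9 and 4.08, the homeobox gene PBX3 by 4.06, 4.29 and 4.07, and YBX3 by 3.74, 3.9 and 4.02. CAV1 (3.78) and SULT1A1 (3.67) led further in InsF, IGF2BP1 (3.6) and PDZRN4 (3.38) in InsG, and IGF2BP1 (3.57) and SULT1A1 (3.55) in InsH.

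The largest falls of these 3 lines overlapped as well. MAP4K1 changed by -2.96, -2.97 and -2.21 in InsF, InsG and InsH, CNTNAP2 by -2.75, -2.24 and -2.50, PPP1R3B by -2.02, -1.97 and -2.05, and P3H3 by -1.93, -1.97 and -1.92. SCD, the stearoyl-CoA desaturase gene, fell by 2.08 ± 0.04 in InsF, where KCNC1 (-1.94), EBF2 (-1.93) and RASL11A (-1.92) followed. CCDC88C (-1.86), MMP1 (-1.82), CRABP2 (-1.78) and KIF1A (-1.66) were among the falls of InsG, and BEND4 (-1.87), MMP1 (-1.81), CRABP2 (-1.79) and CCDC88C (-1.76) among those of InsH.

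In InsF 3461 genes changed (1701 higher, 1760 lower), in InsG 3163 (1534 and 1629) and in InsH 2863 (1392 and 1471). Without control replicate 1 the counts were 1446, 1170 and 1108, and without control replicate 2 they were 1554, 1188 and 1132. Without replicate 1 of the line itself they were 2032, 1228 and 1535, and without its replicate 2 InsF had 2183 and InsH 1837. The splits with limma on log2(TPM + 1) were 1075 higher and 475 lower in InsF, 799 and 385 in InsG, and 900 and 389 in InsH. With library sizes alone they were 2210 and 1336, 2149 and 1195, and 1965 and 1068.

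Across the comparisons with control, 468 genes were higher and 658 lower in all 4 lines, and 2612 of 6053 changed in exactly 1 line, 1508 of them in InsE. Of the 6053 genes, 1871 differed among the lines by edgeR's test. A call in exactly 1 line therefore does not by itself show a difference between lines. InsF and InsH shared 2435 calls of the same direction, against 319 for independent lists, and InsE and InsF shared 1568, against 402. In 30 simulations without change both pairs shared at most 1 call. Such data give almost no calls, so this count cannot serve as a reference for the overlap. Across 13211 genes, the correlation of the log2 changes was 0.88 for InsF and InsH (0.48 simulated) and 0.56 for InsE and InsF (0.48 simulated). The covariance was 0.213 and 0.140, against 0.028 simulated for both pairs. The other pairs of InsF, InsG and InsH had a covariance of 0.205 and 0.212, and InsE with InsG or InsH 0.144 and 0.142 (simulated 0.027 or 0.028). The simulations gave control and lines the same spread and no shared replicate axis, unlike the data. The control libraries were too few to split, so part of the excess covariance may come from the shared controls.

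**Figure D3:**
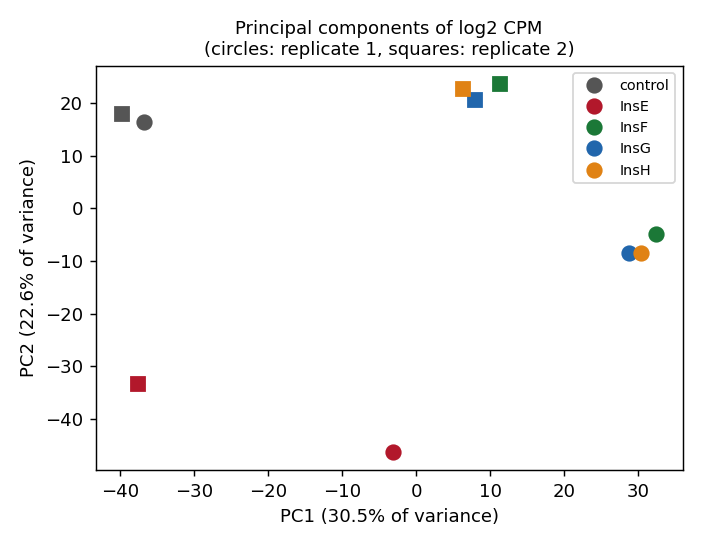
First and second principal component of log2 CPM for the 10 libraries (30.5% and 22.6% of the variance), coloured by group, with circles for replicate 1 and squares for replicate 2. Both control libraries lie together at PC1 of -36.8 and -39.7, and the libraries of each line lie apart by replicate number. InsE replicate 2 lies at PC1 of -37.6, so this axis alone does not separate control from the lines.

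Part of the genes that mark GIST and its counterpart, the interstitial cell of Cajal, fell in the lines. KIT, the receptor tyrosine kinase that drives most GISTs, fell by 0.95 in InsE, 0.79 in InsF, 0.68 in InsG and 0.76 in InsH. Of 17 tested members of this list, 8 fell and none rose in the mean of the lines, with 10 lower and 2 higher when adjusted over the list alone. KIT (-0.80 ± 0.04), ANO1 (-0.77 ± 0.05), PRKCQ (-0.47 ± 0.07) and the transcription factor FOXF1 (-0.44 ± 0.07) led. COL5A3, a collagen gene of the list, fell by 3.07 in InsE and stood at 1.31 in InsF, a call lost without control replicate 2 (adjusted p = 0.151). In InsE COL5A3 stood at 0.08 ± 0.11 CPM, below the floor of 0.319 CPM of InsE replicate 2, so the size of its fall is not settled. For the list of 17 genes the camera adjusted p was 0.0029, and the adjusted p = 0.112 with an estimated correlation. Of 14 tested genes of KIT and PI3K signalling, 4 fell and none rose (5 and 0 adjusted over the list alone), among them the cytokine feedback genes CISH (-0.70) and SOCS1 (-0.48) and FOXO3 (-0.33). The camera adjusted p was 0.0185, and the adjusted p = 0.137 with an estimated correlation. The call of CISH was lost without control replicate 1 (0.0815) and that of SOCS1 without control replicate 2 (0.0728).

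FGF and MAPK output genes moved both ways. DUSP6, a phosphatase gene induced by ERK signalling, stood at 0.24 ± 0.06 in InsE and fell by 1.26, 1.17 and 1.22 in InsF, InsG and InsH. SPRY4, a feedback inhibitor gene of the same pathway, stood at 0.24 in InsE and fell by 0.82, 0.89 and 0.84 in the others. The calls of both in InsE were lost without a library (adjusted p = 0.127 without control replicate 1 for DUSP6 and 0.185 without InsE replicate 2 for SPRY4). SPRY2 rose by 1.00 in InsE and stood at -0.02, -0.01 and -0.05 in InsF, InsG and InsH (among lines, edgeR adjusted p = 1.16e-05). DUSP5, another phosphatase gene of the pathway, stood at 0.33 in InsE and rose by 0.87, 0.93 and 0.85 in InsF, InsG and InsH. Of 18 tested members, 3 rose and 7 fell in the mean, also when adjusted over the list alone (camera adjusted p = 0.231). In InsH 2 rose and 6 fell (camera adjusted p = 0.0472, and adjusted p = 0.21 with an estimated correlation), with a median of -0.15 that became 0.02 with limma on log2(TPM + 1). Of 9 FGF receptors and co-receptors, 5 fell, led by SDC1 (-0.78 ± 0.08) and FGFRL1 (-0.66 ± 0.08), with 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.07), and in InsE 4 fell (camera adjusted p = 0.00709, and adjusted p = 0.189 with an estimated correlation). Of 4 other FGF ligand genes tested, FGF2 fell by 0.51 (0 up and 1 down over the list alone). Its call was lost without control replicate 1 (adjusted p = 0.0621).

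Among the immediate early genes, which respond to growth factors within minutes, some differed between lines. EGR1 stood at 0.55 in InsE and fell by 1.23, 1.27 and 1.15 in InsF, InsG and InsH (among lines, edgeR adjusted p = 4.16e-05), and JUNB fell by 0.96 ± 0.10 in the mean. EGR3 rose by 2.25 ± 0.35 in the mean and stood at 1.48, 2.10, 2.33 and 3.11 in InsE, InsF, InsG and InsH. Its calls were lost in InsE without InsE replicate 1 (adjusted p = 0.326) and in InsF and InsG without control replicate 1 (0.073 and 0.0527). FOS fell by 1.49 ± 0.27 in the mean, a call lost without control replicate 1 (adjusted p = 0.0578). Of 12 tested members, 4 rose and 4 fell in the mean (4 and 5 over the list alone, camera adjusted p = 0.807), and the list's median was 0.08 and, with limma on log2(TPM + 1), -0.2. In InsE 6 rose and 1 fell (camera adjusted p = 0.0302, and adjusted p = 0.371 with an estimated correlation). The call of EGR1 in InsE was lost without control replicate 1 (adjusted p = 0.0769).

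Cholesterol synthesis genes fell in InsF, InsG and InsH and moved both ways in InsE. Of 19 tested members, 15 fell in InsF, 11 in InsG and 10 in InsH with none higher, and in InsE 6 rose and 2 fell. Adjusted over the list alone, 18, 11 and 14 fell, and in InsE 7 rose and 2 fell. MSMO1 changed by -1.05, -0.61 and -0.80 in InsF, InsG and InsH and by 0.09 in InsE, and differed among the lines (edgeR adjusted p = 0.000217). SQLE fell by 0.48 ± 0.04 in the mean. The camera adjusted p was 1.24e-10, 4.56e-07 and 1.87e-08 in InsF, InsG and InsH, with adjusted p = 0.0166, 0.0467 and 0.0282 with an estimated correlation, and 0.107 in InsE. Cholesterol synthesis in these 3 lines gave the only list calls that held with an estimated correlation. In the mean of the lines 9 fell (10 over the list alone), with camera adjusted p = 2.03e-05 and adjusted p = 0.076 with an estimated correlation.

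Most mitochondrially encoded genes fell in the same 3 lines. Of 13 tested, 8, 9 and 8 fell in InsF, InsG and InsH with none higher, and in InsE 3 rose and 1 fell. The list calls of InsF, InsG and InsH (camera adjusted p = 1.05e-05, 2.09e-07 and 3.39e-07) were lost, with adjusted p = 0.132, 0.143 and 0.141 with an estimated correlation. MT-CO3 changed by -0.51, -0.51, -0.52 and 0.06 in InsF, InsG, InsH and InsE (among lines, edgeR adjusted p = 5.7e-05). In the mean 9 fell, also over the list alone (camera adjusted p = 0.00023, and adjusted p = 0.185 with an estimated correlation). The mitochondrial share of counts was 4.19% and 4.13% in the control, 4.66% and 4.67% in InsE, and 3.48% to 3.62% in InsF, InsG and InsH. Of 30 ribosomal protein genes, 8 fell in the mean (8 over the list alone), led by RPL7A (-0.42 ± 0.07), with camera adjusted p = 0.054 and a median of -0.03. With library sizes alone, which moved all lists up alike, it was 0.02, so a direction this small was not settled. In InsE 8 ribosomal protein genes rose and none fell (camera adjusted p = 0.034), and in InsF, InsG and InsH 6, 9 and 6 fell and none rose (0.0175, 2.41e-06 and 0.00383). With an estimated correlation these were adjusted p = 0.545, 0.484, 0.232 and 0.363.

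More matrix, fibroblast and smooth muscle genes rose than fell in InsF, InsG and InsH. Of 22 tested matrix and TGF-beta genes, 12 rose and 3 fell in the mean, the same over the list alone, with COL5A2 (1.73 ± 0.07) and TGFBI (1.37 ± 0.09) after POSTN. LOXL2 (-0.61) and FN1, the fibronectin gene (-0.40), fell and were chosen after their values were seen. In InsE 5 rose and 7 fell, in InsF 12 and 1, in InsG 8 and 3, and in InsH 10 and 3. Of 5 fibroblast markers, 4 rose (DCN, COL14A1 by 1.35, LUM by 0.80 and PDGFRB by 0.47) and THY1 fell by 0.28, the same over the list alone. THY1 was chosen after its values were seen, and its call was lost without control replicate 2 (adjusted p = 0.185). Of the fibroblast markers 2 rose and 1 fell in InsE, and 4 rose and none fell in each other line, with LUM at 0.70, 0.85, 0.87 and 0.76 in InsE, InsF, InsG and InsH. Of 7 smooth muscle markers, 4 rose and 1 fell, the same over the list alone, with ACTA2 at 0.10, 1.11, 0.67 and 0.81 and ACTG2 at -0.38, 2.01, 1.17 and 1.49 in InsE, InsF, InsG and InsH. TAGLN rose by 2.29, 1.32 and 1.69 in InsF, InsG and InsH and stood at -0.83 in InsE, a call lost without InsE replicate 1 (adjusted p = 0.523). MYOCD, a regulator of smooth muscle genes, rose in the mean from 3 control counts, with 10, 43, 52 and 27 counts in InsE, InsF, InsG and InsH, a 16.1-fold ratio in InsF (95% counting interval 5.16 to 81.3). None of the smooth muscle markers rose and 2 fell in InsE, 4 rose in each other line and 1 fell in InsG. The camera adjusted p was 0.00392, 0.00202 and 0.0247 for the 3 lists in the mean, and adjusted p = 0.375, 0.112 and 0.185 with an estimated correlation.

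**Figure D4:**
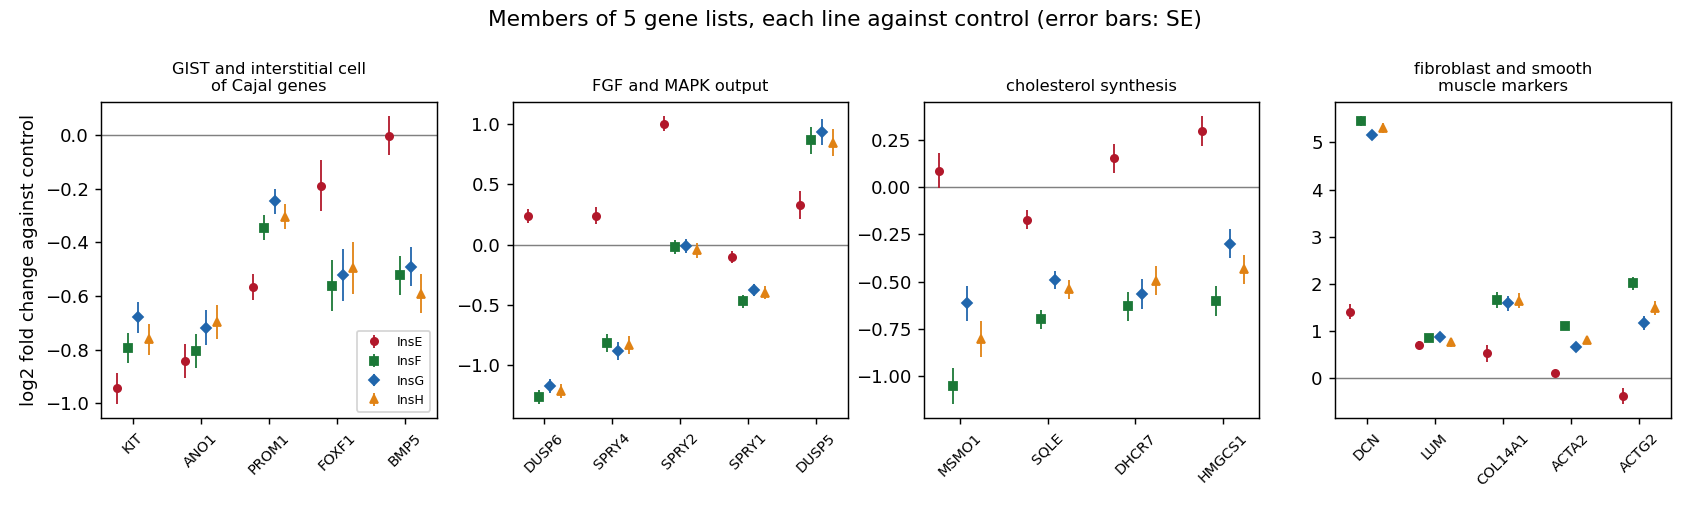
Log2 fold change of each line against control for members of 5 gene lists, with error bars for the SE. KIT and ANO1 lie below 0 in all 4 lines, and DUSP6, SPRY4, MSMO1 and ACTG2 lie on one side of 0 in InsE and on the other in InsF, InsG and InsH.

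DNA methylation genes were lower in part. Of 10 tested, 5 fell in the mean (7 over the list alone), led by TET1 (-0.55 ± 0.06) and UHRF1 (-0.37 ± 0.05), with camera adjusted p = 0.0118 and adjusted p = 0.137 with an estimated correlation. Of 17 CTCF and cohesin genes, 4 fell and 1 rose, the same over the list alone (camera adjusted p = 0.236). CTCF itself changed by -0.20 ± 0.04, a call lost without control replicate 1 (adjusted p = 0.121), and its paralogue CTCFL rose by 1.06 ± 0.11.

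The other lists did not pass the test in the mean of the lines, and 3 of them passed it in at least 1 line. Of 21 SDH and citric acid cycle genes 2 rose and 2 fell (1 and 1 over the list alone, camera adjusted p = 0.903). IDH3A fell by 0.35 ± 0.05. Of 30 cell cycle genes 1 rose and 8 fell, the same over the list alone (0.173), with MKI67 at -0.57 ± 0.04. Of 19 interferon genes 4 rose and 2 fell, the same over the list alone (0.544), with IFIT1 at 0.89 ± 0.07 and OAS3 at -0.73 ± 0.06. The interferon list went one way in InsE, with 2 higher and 6 lower (camera adjusted p = 0.0185), and the other in InsF and InsH. There 6 and 1 (0.0317) and 5 and 1 (0.0321) were higher and lower. With an estimated correlation these lists in InsE, InsF and InsH had adjusted p = 0.157, 0.132 and 0.141. A difference between lines was not tested for this list. Of 8 NF-kB genes 2 rose (3 over the list alone, 0.07), with TNFAIP3 at 0.75 ± 0.05, and in InsH 3 rose and none fell (camera adjusted p = 0.0285, and adjusted p = 0.141 with an estimated correlation). Of 21 p53 targets 5 rose and 3 fell (6 and 3 over the list alone, 0.544), with GDF15 at 1.73 ± 0.19. The test pointed up for the p53 list (median -0.04, mean 0.13) and the SDH list (median -0.01, mean -0.0034), and down for the hypoxia list (median -0.0078, mean 0.13) and the histone list (median 0.05, mean 0.03). The medians of the SDH, cell cycle and p53 lists changed sign with limma on log2(TPM + 1), to 0.03, 0.03 and 0.04, and that of the hypoxia list with upper quartile factors, to 0.02, so directions this small were not settled. Of 20 ER stress and ATF4 genes 6 rose and 2 fell (7 and 2 over the list alone, 0.169), with PHGDH at 0.34 ± 0.04 and SLC7A11 at 0.49 ± 0.11, a call lost without control replicate 2 (adjusted p = 0.11). In InsE 7 of these rose and none fell (camera adjusted p = 0.00267, and adjusted p = 0.0926 with an estimated correlation). Of 19 hypoxia and glycolysis genes 4 rose and 3 fell, the same over the list alone (0.807), with HK2 at -0.38 ± 0.04. SLC2A3, a glucose transporter gene, had 3 control counts and 7, 23, 40 and 27 counts in InsE, InsF, InsG and InsH, a 12.2-fold ratio in InsG (95% counting interval 3.88 to 61.5). Its call in the mean was lost without InsE replicate 1 (adjusted p = 0.994).

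Of 7 HOXA genes 3 rose and 2 fell (4 and 2 over the list alone, 0.759), with HOXA13 at -1.26 ± 0.10 and HOXA3 at 1.27 ± 0.25, a call lost without control replicate 1 (adjusted p = 0.0804). Of 21 clustered protocadherins 3 rose and 2 fell (1 and 2 over the list alone, 0.591), with PCDHB13 at -1.14 ± 0.23, a call lost without control replicate 1 (adjusted p = 0.105). None of 10 replication histone genes was called (0.903), also over the list alone. Markers of other cell types had at most 3 tested members per list. Of these, TUBB3 of the neural list (-0.46 ± 0.06), KRT18 of the epithelial list (-0.35 ± 0.08) and ERG of the endothelial list (-1.27 ± 0.34) fell, each as 1 of 3 tested. Over the list alone 1 neural gene and 3 epithelial genes fell, and 1 endothelial gene rose and 1 fell. The calls of KRT18 and ERG were lost without control replicate 2 (adjusted p = 0.101) and control replicate 1 (0.181). The 1 tested blood cell or mast cell marker was not called.

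The 4 lines also differed from each other. SCD stood at 862 ± 5.1 CPM in InsE and at 229 ± 1.8, 354 ± 6.3 and 315 ± 7.0 in InsF, InsG and InsH, against 968 ± 6.0 in the control. WISP1, a matricellular protein gene, fell by 1.32 in InsE and rose by 2.75, 2.23 and 2.33 in the others. ECM1 fell by 2.92 in InsE and stood at 0.60, 0.38 and 0.53 in the others. With DCN and DUSP6 these had the smallest p among the lines (edgeR adjusted p from 7.94e-08 to 4.24e-06). Among the lines 2055 genes differed, 700 without InsE replicate 1 and 952 without InsE replicate 2. InsE differed from InsF in 2895 genes, from InsG in 2689 and from InsH in 2260. InsF differed from InsG in 27 and from InsH in 11, and InsG from InsH in 0 (edgeR). For InsG and InsH 608 of 15554 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that no difference would give. DESeq2 called 2. These counts and those against the other groups come from the fit without a term for the replicate number, which separated the libraries of the lines. With such a term more genes differed among the lines and stood apart for each group, as given with the processing below. Pairs of lines were not tested with it, so the small counts do not show that InsF, InsG and InsH were alike. Against the mean of the other 4 groups, 4296 genes stood apart for control, 3598 for InsE, 919 for InsF, 364 for InsG and 263 for InsH. For InsE this count was 1704 without its replicate 1 and 1978 without its replicate 2. With the controls merged it was 1690 for control and 2615 for InsE, so that the order of these 2 turned.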

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

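The tests of the control spread and the shallow InsE library, and the weighing of a control batch, in this part were chosen only after the result was seen, and the tests of the replicate axis, of GC content and transcript length and of copy number were chosen before.

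The change against control differed between the lines, by edgeR's test of any difference among InsE, InsF, InsG and InsH, for 2055 genes, and whether this comes from the disruption or from other differences of the lines was not tested. It differed for FGF3 (adjusted p = 4.13e-05), CCND1 (1.16e-05), SCD (7.94e-08), WISP1 (7.94e-08), DCN (9.64e-08), DUSP6 (1.55e-06) and ECM1 (4.24e-06). Without InsE replicate 1 the count of genes was 700, and without InsE replicate 2 it was 952.

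The first pattern was the 4296 genes changed in the mean of the 4 lines against control. After a smooth trend of each library on GC content and transcript length was removed, 96.6% of them passed with the same sign (6269 calls in all), which argues against such a trend as the whole cause. The control libraries lay closer together than those of any line, and with both merged into 1 library 39.2% (1684 genes) passed with the same sign, which argues against too small a control spread for these, while for the other 2612 it stays open, since the merged fit also has fewer libraries. For all 4296 genes a batch of the control libraries and an effect shared by the lines cannot be told apart, because a control batch would coincide with the control group. The same holds for any other trait that sets the control line apart, such as its history as a line, because no other control line was profiled. The change had a correlation of -0.29 across 12167 genes with the axis between replicates 1 and 2 of the lines, between the bounds of 0.2 and 0.5 set for it, so part of the pattern may follow that axis, and the insulator disruption itself also stays open.

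The second pattern was InsE set apart from the other groups, with 3598 genes differing from their mean, 1704 without InsE replicate 1 and 1978 without InsE replicate 2. In the fit without InsE replicate 2, the shallowest library, over all genes, InsE stood apart in 1978 genes, against 823 for InsF, 257 for InsG and 229 for InsH, which argues against this library as the whole cause. After the correction for GC content and transcript length 94.9% passed with the same sign, which argues against that trend. Bins of 10 Mb accounted for 2.5% of the variance of the InsE difference across 12047 genes, which argues against copy number as the whole cause. What distinguishes InsE biologically, in its edit or its history as a line, was not tested and stays open.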

How the results depend on the processing

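The merging of the control libraries and the block within the 4 lines were chosen only after the result was seen. FGF3 passed the threshold in the same direction in each line, and differed among the lines, under all alternatives run on it. Its fitted log2 changes rest on the prior count, with no control counts, and are not given. Without 1 library its adjusted p among the lines was 2.2e-05 to 0.00158. RLE and upper quartile factors, library sizes alone, the stricter filter, unrounded counts, limma-voom and pairs of groups alone kept each count of changed genes within 1.5 times. Counts are given in the order InsE, InsF, InsG, InsH, mean of the lines and differences among the lines. Without 1 library they ran from 1429 to 2603, 1446 to 2183, 1170 to 2470, 1108 to 1837, 1501 to 4311 and 700 to 1873. With limma on log2(TPM + 1) they were 1700, 1550, 1184, 1289, 2073 and 904, with log2(TPM + 0.1) 1723, 1559, 1214, 1303, 2119 and 923, and on log2(TPM + 1) with no filter 1176, 1144, 756, 937, 1510 and 564. At an adjusted p under 0.01 they were 1763, 1705, 1417, 1337, 2304 and 908, which the threshold itself brings. With an absolute log2 change of at least 1 they were 611, 659, 546, 545 and 591. With the controls merged they were 1639, 1565, 1226, 1180, 1690 and 1273. DESeq2 gave 2212 in InsF, 2065 in InsG and 1856 in InsH. Among the lines 3660 genes differed with no low-count filter and 1351 with the 4 lines alone. Against the mean of the other 4 groups, InsE had 2332 genes with DESeq2, and with the controls merged control had 1690, InsF 493, InsG 123 and InsH 134. With an estimated correlation 0 lists passed camera in InsE, 1 each in InsF, InsG and InsH and 0 in the mean, and fry passed 14 in InsE, 18 in InsG and 18 in the mean. Within 1 Mb of FGF3 the odds ratios in InsE, InsF, InsG, InsH and the mean were 2.49, 5.69, 3.57, 4.04 and 8.41. There InsE passed too (Fisher's exact p = 0.0402). Within 5 Mb the ratios were 0.82, 1.23, 1.19, 0.988 and 1.24, of which none passed and those of InsE and InsH reversed. Of the named genes, IDH3A in InsG reversed on log2(TPM + 1), with and without the filter, and on log2(TPM + 0.1) (IDH3A, InsG against control, 0.0556 and 0.0555), as did CENPF in the mean (CENPF, mean of the 4 insulator lines against control, 0.0382 and 0.0384). Over 532 results of the genes reported here, alternatives left 9274 values on their side of the threshold, lost 1795 calls, gained 37 and reversed 6. A lone library left in a group was assumed to vary like the other groups. Except for the change of threshold, the cause was not tested.

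Same-numbered libraries deviated together among the 4 lines (correlation of 0.59 to 0.68) and not between control and lines (-0.01 to 0.08). The labels do not say what a replicate number marks and there are 2 numbers, so the pairing is a hint from the data and not part of the design. With a replicate block the counts were 5935, 5886, 5769, 5317, 6679 and 5442, and against the mean of the other groups 6679 for control, 5719 for InsE, 2731 for InsF, 3000 for InsG and 1159 for InsH. With the block within the 4 lines only the counts were 7783, 7772, 7666, 7131, 8393 and 8599.

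Depth limited FGF4, FGF19, MYEOV, SLC2A3 and MYOCD, which had at most 52 counts over both libraries of a line and at most 6 over both control libraries. InsE replicate 2, with 9.4 M counts, had the highest floor for a gene at 0, at 0.319 CPM. The mean levels of PRSS35 and COL5A3 in InsE lay below this floor.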

Other observations

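All tests in this part were chosen only after the result was seen, and the 2 regions and their genes were chosen after their values were seen.

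Genes at the far end of chromosome 13 were higher in all 4 lines. Counts and medians for the regions and for genes elsewhere cover tested genes with a mean log2 CPM of at least 1. Of 86 such genes from MZT1 (72708357, hg38) to position 114337626, 75 were higher in the mean of the lines, and 58 rose and 4 fell by edgeR's test. SLITRK6, a membrane protein gene of neurons, rose by 1.70 ± 0.09 in that mean (log2 ± SE), GPC6, a glypican gene, by 1.28 ± 0.08, LAMP1, a lysosomal membrane gene, by 0.51 ± 0.05 and PCCA, a propionyl-CoA carboxylase gene, by 0.66 ± 0.06, while TBC1D4, a regulator of glucose transport, fell by 0.83 ± 0.06. The median change was 0.42 (quartiles 0.18 and 0.54), and 0.07 for the 138 tested genes on the rest of the chromosome. At the end of chromosome 4 (39 genes from 171812254 to 190027257) 34 were higher, 17 rose and 2 fell, and the median was 0.23, against 0.00 for the other 388.

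A further pattern was this shift of the 2 regions. In each region 87.2% of genes were higher, against 48.6% and 48.9% elsewhere. The regions were chosen for being higher, so this share does not decide whether a few strongly changed genes drew the choice. After the correction for GC content and transcript length the chromosome 13 median was 0.4 (95% bootstrap interval 0.31 to 0.46) and the chromosome 4 median was 0.2 (0.12 to 0.32), which argues against that trend as the whole cause in both. On chromosome 4 the lower end lay at 0.5 of the uncorrected median (0.12), so a part of up to about that size stays open there, and neighbouring genes may not be independent, which would widen the intervals. The medians of InsE, InsF, InsG and InsH were 0.36, 0.36, 0.47 and 0.39 on chromosome 13 and 0.24, 0.25, 0.30 and 0.23 on chromosome 4, a widest range of 0.11. The lines share their controls, so this agreement decides between no explanations. As a hypothesis, a copy number difference between the control line and the cells from which the 4 lines were derived may account for these shifts, as may an expression effect shared by the lines. Copy number measured in DNA of the control and the 4 lines over both regions would decide this, and no DNA was measured here.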
